A study of Mus musculus with 9 samples.

How the data were processed

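The series holds RNA-seq of mouse 4T1 mammary carcinoma cells in 9 libraries, 3 with a control hairpin (shCTRL) and 3 each with hairpins shYap-1 and shYap-2 against Yap1. Per the labels, RNA was taken up in Trizol, enriched with oligo(dT), prepared with a NEBNext Ultra kit and sequenced on a Novaseq6000. The authors gave gene values as FPKM, fragments per kilobase of transcript and M mapped fragments, rounded to 2 decimals, in 2 tables, one per hairpin. Their notes name fastp 0.18.0, HISAT2 2.1.0, StringTie 1.3.4, RSEM without a version and the mm10 build, without saying which step each served. Annotation, filters and use of strand are not stated. Both tables carry the 3 shCTRL libraries, and 0 of their values differ between tables for shared genes. The tables hold 16530 and 16358 genes, of which 38 and 34 are 0 in every library. GENCODE vM21 gave symbols, lengths, GC content and positions (GRCm38) for 16951 of the 16962 gene identifiers. Groups were taken from the sample labels.

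Depth was estimated from the values themselves, as the depth at which FPKM times exonic length gives whole numbers of fragments in genes of low abundance with 1 annotated transcript. Tested on simulated data, the largest error was 0.05 M fragments. Replicate variance was compared with sampling noise in genes with 1 annotated transcript, where a ratio of 1 means sampling noise alone.

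Each hairpin was tested against shCTRL within its own table with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend on abundance) on log2(FPKM + 1). Genes with FPKM of at least 1 in at least 3 of the fitted libraries were tested, without further scaling, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The mean of both hairpins against shCTRL and shYap-2 against shYap-1 came from 1 model of all 9 libraries. Genes changed with both hairpins in the same direction were counted beside the product of the list sizes over the genes tested, and beside 100 simulations. Each simulation drew unchanged groups and the controls they share as noise independent between genes. The smallest exact permutation p for 3 libraries against 3 is 0.1, so p-values below it rest on the model. The fits were tested on simulated data in which 200 genes changed, 100 by 0.5 and 100 by 1 on the log2 scale. Of changes of 0.5, 66.9% were recovered with shYap-1, 94.5% with shYap-2, 87.2% for the mean and 79.3% for the difference. At a change of 1 these were 98.6%, 99.8%, 99.6% and 98.8%. Over both sizes together, 5.48%, 6.0%, 5.04% and 4.61% of calls were false. Each hairpin changed far more genes against shCTRL than were changed here, so these shares need not hold for the data.

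Gene lists were tested with camera (limma) at a preset correlation between genes of 0.01, with an estimated correlation and with fry as alternatives. There were 23 lists, of which 20 had at least 5 measured members and were tested; MHC class II and the markers of leukocytes and of fibroblasts and endothelium had fewer. In 1 simulated data set with 1 changed list among 20, camera called that list and 0 of the others. Its genes were drawn independently, so it does not test the preset correlation. The comparisons, tests, lists, naming rule and most alternatives were chosen before the data were examined. Genes were named by this rule: Yap1 and Wwtr1; called members of the MHC class I and YAP/TAZ lists, and 9 of their members whatever their p; the 10 largest rises and falls shared by both hairpins, the 5 largest of each hairpin and the 5 largest differences between hairpins in each direction. These had to have a mean FPKM of at least 5 in the higher group and replicate values without overlap, and gene models and pseudogenes were left out. From every other list up to 4 members with the smallest adjusted p for the mean of both hairpins were named.

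The alternatives were a pseudocount of 0.1, no filter, FPKM of at least 5 in 3 libraries, trimmed-mean and median-of-ratios scaling, limma without trend, a replicate block, each library left out, a size threshold of 1 on the log2 scale and all 9 libraries in 1 fit. Removal of a trend on GC content from each library, and 6 further gene lists, were chosen after seeing the data. Tables and simulations of depth were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures with matplotlib 3.10.9. Tools for counts were not used, since the values are FPKM. Raw reads were not used here.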

Results

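RNA of 4T1 cells, a mouse mammary carcinoma line derived from a BALB/c mouse, was sequenced in 9 libraries. They form 3 groups of 3 replicates, one with a control hairpin (shCTRL) and 2 with different hairpins against Yap1 (shYap-1 and shYap-2). Yap1 encodes YAP, the transcriptional co-activator that the Hippo kinase cascade restrains, and the series asks what changes after its knockdown, with antigen processing and presentation by MHC class I named in its title. The labels do not say whether replicates came from separate cultures, so every p-value measures only the spread between these libraries. Gene abundance is given as FPKM, for 16530 genes beside shYap-1 and 16358 beside shYap-2, of which 15926 were in both. The depth behind the values was estimated at 24.45, 22.1 and 24.3 M fragments for shCTRL replicates 1, 2 and 3. For shYap-1 it was 28.3, 19.55 and 24.45 M, and for shYap-2 it was 26.85, 27.55 and 21.8 M. A transcript of 1 kilobase with an FPKM of 1 therefore rests on about as many fragments as the library has M, which covers counting error only.

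The libraries separated by group. The first principal component held 85.5% of the variance and placed the 3 shCTRL libraries on one side and all 6 knockdown libraries on the other. Replicate variance was 2.33 to 4.23 times the sampling noise between shCTRL libraries and 1.68 to 2.07 times between shYap-2 libraries. In shYap-1 it was 1.99 between replicates 1 and 3, but 16.1 and 13.1 where replicate 2 took part. That library stood apart on the second component (6.53% of the variance), had 2.01% of its FPKM in mitochondrially encoded genes against 4.23% and 3.97% in replicates 1 and 3, and deviated from them by gene GC content (Spearman rho 0.706 across 10731 genes, which are not independent replicates). The same GC measure was -0.641 and -0.555 for shYap-1 replicates 1 and 3, and -0.38, 0.005 and 0.386 for shCTRL replicates 1, 2 and 3. For shYap-2 it was -0.194, 0.092 and 0.094. The Yap1 level of shYap-1 replicate 2 lay between those of its fellow replicates.

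Yap1 fell with both hairpins. Its FPKM was 49.3, 48.3 and 48.8 in the shCTRL libraries, 8.03, 9.05 and 9.23 with shYap-1, and 11.04, 10.4 and 9.79 with shYap-2. The means were 48.8 ± 0.475 (SD, n = 3), 8.77 ± 0.647 (SD, n = 3) and 10.4 ± 0.626 (SD, n = 3). Yap1 (ENSMUSG00000053110) lies on chromosome 9 from 7931999 to 8004596 in GRCm38. Its log2 fold change was -2.35 with shYap-1 (SE 0.0701, limma, Benjamini-Hochberg adjusted p = 9.3e-07) and -2.13 with shYap-2 (SE 0.0496, adjusted p = 4.26e-09). All log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. The paralog Wwtr1, which encodes TAZ, fell slightly, by 0.22 with shYap-1 (adjusted p = 0.00978) and by 0.24 with shYap-2 (adjusted p = 0.000342). The call of Wwtr1 with shYap-1 ended when the trend on GC content was removed from each library (-0.15).

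**Figure D1:**
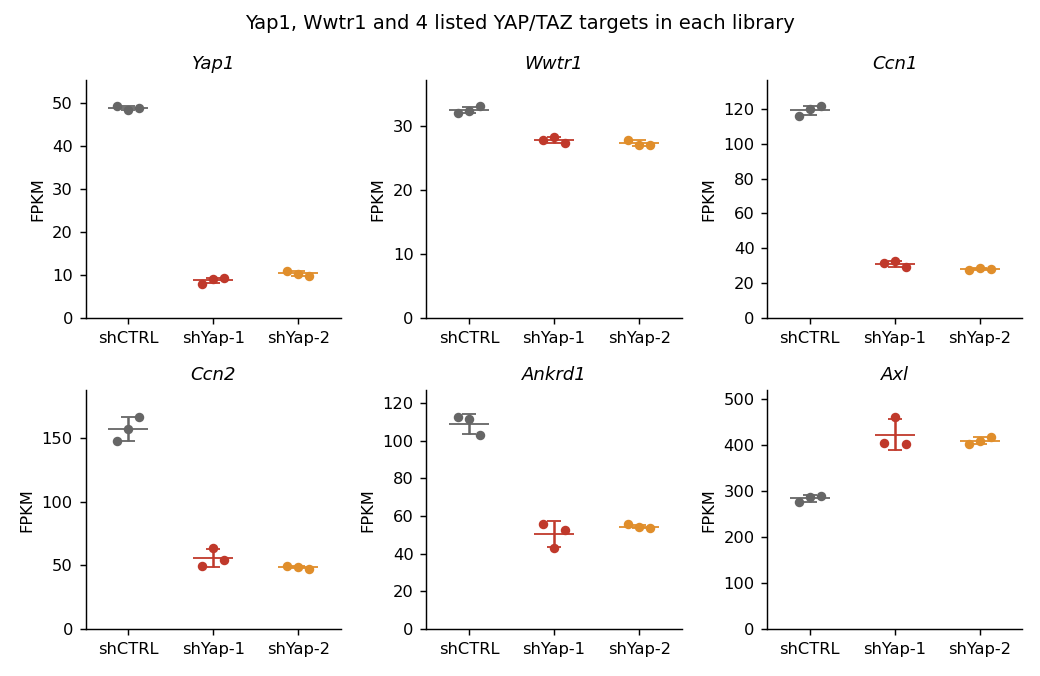
FPKM of Yap1, Wwtr1 and 4 listed YAP/TAZ targets in the 9 libraries, by group (points, libraries; bars, mean and SD of 3 replicates). The 6 knockdown libraries lie between 8.03 and 11.04 FPKM for Yap1 against 48.3 to 49.3 in shCTRL, and Axl is higher in the knockdown groups.

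Direct YAP/TAZ target genes fell with Yap1. Ccn1 and Ccn2, which encode matricellular proteins and are standard readouts of YAP activity, fell by 1.90 and 1.48 with shYap-1 and by 2.03 and 1.68 with shYap-2. Ankrd1 (-1.10 and -0.99) and Amotl2 (-1.23 and -1.20), a Hippo scaffold gene and YAP target, also fell. Of 16 measured members of a published YAP/TAZ signature, 11 fell and 2 rose with shYap-1 (median -0.76), and 12 fell and 1 rose with shYap-2 (median -0.65). Nt5e (-1.25 and -1.14), Gadd45b (-1.15 and -1.22), Asap1 (-1.08 and -0.96), Lats2 (-0.82 and -0.74), Myof (-0.70 and -0.57) and F3 (-0.64 and -0.47) fell with both. Ptpn14 fell by 0.23 with shYap-1, a call that ended without any one shCTRL library or without shYap-1 replicate 1 or 3, and by 0.21 with shYap-2. Dock5 fell by 0.14 with shYap-2 and had -0.08 with shYap-1 (adjusted p = 0.291), where either scaling or the removal of the GC trend made it a call. Axl, a receptor tyrosine kinase gene of that signature, rose with both (0.57 and 0.53). Crim1 rose with shYap-1 (0.33, adjusted p = 0.0253), a call that ended with either scaling between libraries (0.23 and 0.24), with the GC trend removed (0.23), and without shCTRL replicate 1 or 2 (0.28 and 0.31). With shYap-2 Crim1 had 0.05 (adjusted p = 0.471), and 0.11 (adjusted p = 0.0332) without shCTRL replicate 3. The signature was lower than other genes in a competitive test (camera, adjusted p = 0.000283 with shYap-1 and 7.22e-05 with shYap-2). With an estimated correlation between genes, the adjusted p = 0.0359 and 0.0866. The Hippo pathway list as a whole was not called (adjusted p = 0.468 and 0.281). Within it, 8 genes rose and 10 fell of 28 with shYap-1, and 10 rose and 13 fell with shYap-2. The scaffold gene Amot (1.55 and 1.37) and Limd1 (0.84 and 0.79) rose, whereas Tead1, which encodes a DNA-binding partner of YAP, fell (-1.14 and -0.90).

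Genes of MHC class I antigen processing and presentation rose with both hairpins. H2-K1, a classical heavy chain gene on chromosome 17 (33996017 to 34000347), went from 33.7 ± 1.94 FPKM (SD, n = 3) in shCTRL to 83.1 ± 7.38 (SD, n = 3) with shYap-1 and 70.3 ± 1.34 (SD, n = 3) with shYap-2. The light chain gene B2m, on chromosome 2 (122147686 to 122153083), went from 282.1 ± 10.9 FPKM (SD, n = 3) to 737.7 ± 48.0 (SD, n = 3) and 623.4 ± 22.8 (SD, n = 3). H2-D1 rose by 1.41 and 1.14 on the log2 scale. The peptide transporter gene Tap1 rose by 2.40 (SE 0.0883) and 1.92 (SE 0.0885). The immunoproteasome genes Psmb8 (1.86 and 1.46) and Psmb9 (1.92 and 1.58) rose, as did Calr (1.45 and 1.27), a chaperone gene of peptide loading, and Nlrc5 (1.32 and 1.10), which encodes a transactivator of these genes. Tapbpl (1.51 and 1.21), Erap1 (1.35 and 1.16), Tapbp (1.28 and 1.03), Psme1 (1.09 and 0.95), Psme2 (1.08 and 0.93), Tap2 (1.05 and 0.95), Psmb10 (0.99 and 0.71) and Pdia3 (0.79 and 0.71) rose too. With shYap-1, 16 of 17 measured members rose (median 1.32, adjusted p = 5.06e-07, and 0.0359 with an estimated correlation). The call with an estimated correlation ended without shYap-1 replicate 2. With shYap-2, all 17 rose (median 1.10, adjusted p = 5.74e-07; adjusted p = 0.0892 with an estimated correlation). The exception, the chaperone gene Canx, had 0.24 with shYap-1 (adjusted p = 0.117), and 0.39 (adjusted p = 8.52e-05) without shYap-1 replicate 2 and 0.34 (adjusted p = 0.000759) with the GC trend removed. With shYap-2 it rose by 0.20 (adjusted p = 0.000178), a call that ended with all 9 libraries in 1 fit (adjusted p = 0.117). That fit takes a common variance from all groups, and Canx had an SD of 27.1 FPKM with shYap-1 and 1.43 with shYap-2. The reference genome carries another H2 haplotype than BALB/c, H2-L has no value in either table, and the sharing of reads among H2 genes was not tested. Tap1 and Psmb9 overlap at their ends, and the use of strand in the values is not stated.

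**Figure D2:**
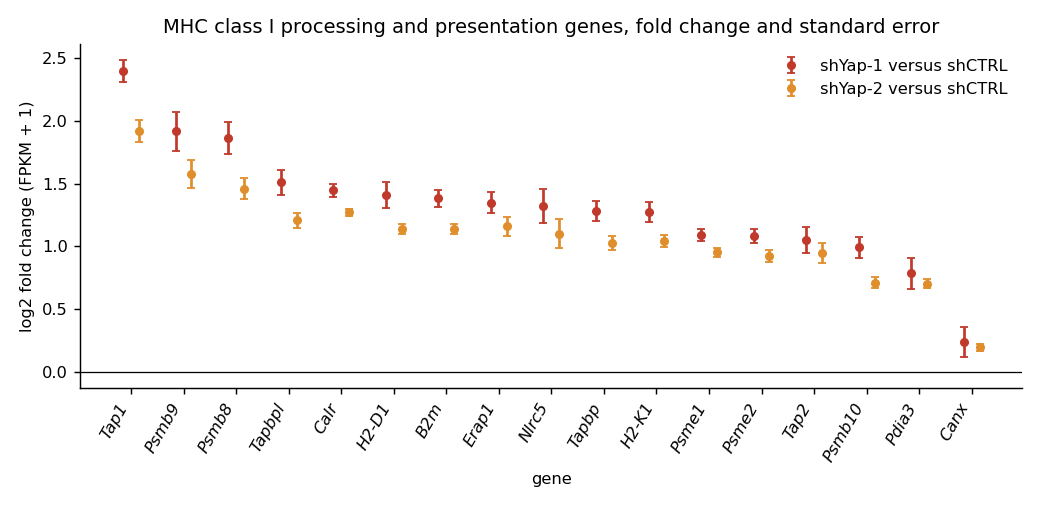
Log2 fold change (FPKM + 1) of 17 genes of MHC class I processing and presentation with each hairpin against shCTRL (points, 3 libraries against 3; bars, standard error). All 17 lie above 0 with both hairpins, from Canx (0.24 and 0.20) to Tap1 (2.40 and 1.92).

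Interferon-response genes rose with both hairpins. Irf7, which encodes a transcription factor of the type I interferon response, went from 0.82 ± 0.221 FPKM (SD, n = 3) to 65.5 ± 6.77 (SD, n = 3) with shYap-1 and 45.8 ± 4.74 (SD, n = 3) with shYap-2, and had the largest rise with either hairpin (5.19 and 4.69). Isg15, a ubiquitin-like modifier gene, rose by 4.19 and 3.68, and Usp18, whose product removes ISG15 from proteins, by 4.45 and 3.83. Ifit1 (4.32 and 3.75), Xaf1 (4.22 and 3.70), Oas1a (4.12 and 3.56), Oas3 (4.07 and 3.54), Oasl2 (3.99 and 3.51), Dhx58 (3.91 and 3.44) and Zbp1 (3.83 and 3.40) complete the 10 largest shared rises under the naming rule, which leaves out genes known only as gene models. In the type I interferon list, 35 of 36 measured members rose with shYap-1 (median 2.52) and 34 of 35 with shYap-2 (median 2.19). The exception with both was Ifit2, singled out after its values were seen (0.10, adjusted p = 0.543, and -0.19, adjusted p = 0.173). In the interferon-gamma list, 16 of 18 rose with shYap-1 (median 1.89) and 17 of 18 with shYap-2 (median 1.56). Igtp (3.43 and 2.94), Irgm2 (3.01 and 2.60), Gbp3 (3.0 and 2.51) and Gbp7 (2.97 and 2.42), all interferon-inducible GTPase genes, are examples. Camera called both lists with shYap-1 (adjusted p = 2.19e-15 and 2.62e-06, and 0.0359 for each with an estimated correlation). It called both with shYap-2 as well (adjusted p = 3.81e-13 and 1.86e-05), but with an estimated correlation the adjusted p = 0.153 and 0.0866. Irgm2 spans most of Igtp, and Oas1a has close relatives such as Oas1g, so the split of reads among these genes is uncertain.

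Other genes of antigen presentation rose in part. H2-T23 (2.42 and 2.07), H2-T24 (2.28 and 1.94), H2-T22 (1.59 and 1.33) and Cd1d1 (1.67 and 1.39) rose among the non-classical and MHC-like genes. Of that list, 7 rose and 1 fell of 12 with shYap-1 (median 0.85, adjusted p = 0.0452), and 8 rose and 2 fell of 13 with shYap-2 (median 0.68, adjusted p = 0.0832). With an estimated correlation the adjusted p = 0.165 and 0.348. The call with shYap-1 also ended without shYap-1 replicate 1, 2 or 3 (medians 0.23, 0.10 and 0.17), when genes near 0 in shCTRL left the test, and without shCTRL replicate 1 (median 0.84, adjusted p = 0.0513). It ended likewise with a pseudocount of 0.1 (adjusted p = 0.0518), with the stricter filter (0.0933 as adjusted p) and with the GC trend removed (adjusted p = 0.0554). Of 10 MHC class II genes with values, H2-DMa (3.34 and 3.05) and Cd74 (1.24 and 0.92), which encodes the invariant chain, passed the filter and rose. Of 10 measured ligands of immune checkpoints, 5 rose and 3 fell with shYap-1, and 4 rose and 3 fell with shYap-2. This list was not called (adjusted p = 0.5 and 0.664). Lgals9, which encodes galectin-9, rose most (2.85 and 2.44). Cd276, which encodes B7-H3, rose (1.38 and 1.13), Cd24a rose (0.64 and 0.55), and Nt5e, which encodes the ectonucleotidase CD73, fell. Of 15 leukocyte marker genes with values, 1 exceeded 1 FPKM in some group, Cd68, which fell (-0.75 and -0.67). Of 16 fibroblast and endothelial markers, 1 did, Pdgfra, which also fell (-0.64 and -0.60).

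Genes of the integrated stress response fell with both hairpins. Trib3, a pseudokinase gene, went from 121.2 ± 8.54 FPKM (SD, n = 3) to 10.4 ± 1.93 (SD, n = 3) with shYap-1 and 9.24 ± 0.119 (SD, n = 3) with shYap-2 (-3.43 and -3.58). Chac1, whose product degrades glutathione (-3.19 and -3.17), and the mTORC1 inhibitor gene Ddit4 (-2.97 and -2.94) followed. Atf4, which encodes a transcription factor of this response (-1.84 and -1.78), and its target Asns, asparagine synthetase (-2.0 and -1.94), fell too. Of 25 genes of the unfolded protein and integrated stress response, 18 fell and 4 rose with either hairpin (medians -1.44 and -1.49, adjusted p = 1.07e-06 and 4.09e-07). With an estimated correlation the adjusted p = 0.0359 and 0.0892. The 4 that rose, named after their values were seen, were Dnajb9, Creld2, Manf and Hspa5 (0.25 and 0.21), which encode chaperones and other proteins of the endoplasmic reticulum.

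Ribosomal protein genes fell together. With shYap-1, 40 of 42 fell (42 adjusted over the list alone, median -0.53), and with shYap-2 all 42 fell (median -0.45). Rpl3 (-0.86 and -0.71), Rps6 (-0.82 and -0.70) and Rpl7 (-0.73 and -0.57) are examples. Camera gave adjusted p = 8.2e-13 with shYap-1 (0.0359 with an estimated correlation) and 8.58e-17 with shYap-2 (adjusted p = 0.0866 with an estimated correlation). These genes have many processed copies in the genome, so single values are less certain than the group's.

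Cell cycle genes fell, more with shYap-1 than with shYap-2. Of 33 genes of S phase and G2/M, 28 fell and 1 rose with shYap-1 (30 fell adjusted over the list alone, median -0.75), and 27 fell and 3 rose with shYap-2 (median -0.39). The ribonucleotide reductase gene Rrm2 (-1.55 and -1.23), Ccna2, which encodes cyclin A2 (-1.13 and -0.73), the replicative helicase gene Mcm7 (-1.11 and -0.73) and Ube2c (-1.04 and -0.72) are examples. Of the risers, named after their values were seen, Ccne1 rose with both (0.38 and 0.68), and Ccne2 (0.50) and E2f1 (0.21) with shYap-2. The adjusted p = 1.79e-10 and 6.16e-08, or 0.0359 and 0.0892 with an estimated correlation. Myc fell by 1.34 and 1.20.

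Sterol synthesis, chemokine and hypoxia genes also fell. In sterol synthesis and uptake, 15 of 22 genes fell and 2 rose with shYap-1 (median -0.38), and 14 fell and 5 rose with shYap-2 (median -0.22). Examples are Fdps (-1.29 and -0.91), Fdft1 (-1.01 and -0.72) and Mvd (-1.16 and -0.88), all enzymes of the mevalonate and squalene steps. The adjusted p = 0.000358 and 0.00348, or 0.0359 and 0.153 with an estimated correlation. Among 22 NF-kB targets, cytokines and chemokines, 16 fell and 2 rose with shYap-1 (3 rose adjusted over the list alone, median -0.58), and 18 fell and 3 rose with shYap-2 (median -0.54). The neutrophil chemokine genes Cxcl5 (-3.01 and -2.77) and Cxcl1 (-2.91 and -2.60) and the chemokine gene Ccl20 (-2.43 and -2.37) fell most. The adjusted p = 5.22e-05 and 2.11e-05, and adjusted p = 0.154 and 0.159 with an estimated correlation. Of 26 glycolysis and hypoxia genes, 15 fell and 4 rose with shYap-1 (median -0.38), and 18 fell and 6 rose with shYap-2 (median -0.38). The angiogenic factor gene Vegfa (-2.46 and -2.36), Ndrg1 (-1.03 and -1.26) and the glycolytic enzyme gene Pgk1 (-0.94 and -0.89) fell. The adjusted p = 0.000617 and 9.67e-05, and adjusted p = 0.3 and 0.278 with an estimated correlation.

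Other lists moved in both directions or weakly. Among mesenchymal and matrix genes, 16 of 23 rose and 3 fell with shYap-1 (median 0.49, adjusted p = 0.0179), and 15 rose and 2 fell with shYap-2 (median 0.35, adjusted p = 0.0667). With an estimated correlation the adjusted p = 0.321 and 0.412. The second was called when any one of the 3 shCTRL libraries was left out (medians 0.35, 0.35 and 0.39, adjusted p = 0.0326, 0.0321 and 0.0265). Timp1 (0.91 and 0.81), Mmp9 (1.00 and 1.07) and Itga5 (1.00 and 0.86) rose, and Thbs1 fell (-1.17 and -1.29). TGF-beta response genes were not called (11 of 17 rose, adjusted p = 0.0859, and 10 rose, adjusted p = 0.162), although Id2 (1.97 and 1.55) and Id3 (1.18 and 0.88) rose and Tgfbr2 fell (-1.01 and -0.93). Among 19 epithelial genes, 6 rose and 7 fell with shYap-1 and 6 rose and 8 fell with shYap-2 (adjusted p = 0.629 and 0.642). The medians were 0.04 and 0.05, while the test placed the list below other genes. The keratin genes Krt14 (1.79 and 1.36) and Krt19 (1.42 and 1.16) rose, and Grhl2 fell (-0.87 and -0.83). Among 19 p53 targets and apoptosis genes, 8 rose and 7 fell with shYap-1 (8 fell adjusted over the list alone), and 8 rose and 10 fell with shYap-2 (adjusted p = 0.557 and 0.405). With shYap-1 their median was -0.14 and their mean 0.03. Fas (1.83 and 1.51) and Phlda3 (1.46 and 1.26) rose, and Gadd45a fell (-1.35 and -1.61). Of 20 immediate early genes, 5 rose and 10 fell with shYap-1, and 7 rose and 9 fell with shYap-2 (adjusted p = 0.115 and 0.162), with Atf3 (-1.88 and -2.13) and Egr1 (-1.36 and -0.99) among those that fell. Of 28 nuclear genes of oxidative phosphorylation, 12 rose and 2 fell with shYap-1 (11 rose adjusted over the list alone), and 18 rose and 2 fell with shYap-2 (adjusted p = 0.153 and 0.0747). Ndufa9 (0.57 and 0.46) is an example. Of 13 mitochondrially encoded genes, 0 passed with shYap-1 (limma, 0 also at unadjusted p under 0.05; median -0.03), and shYap-1 replicate 2 lay 1.07 below its fellow replicates in the list's median. Without that library 9 of the 13 rose with shYap-1 (median 0.34). With shYap-2, 1 rose and 3 fell (1 and 2 adjusted over the list alone), the median was 0.02 and the mean -0.02. The calls of mt-Cytb (0.25, higher), mt-Nd5 (-0.37) and mt-Nd6 (-0.50) ended with all 9 libraries in 1 fit (adjusted p = 0.308, 0.205 and 0.341). That fit takes a common variance from all groups, and mt-Cytb had an SD of 671.6 FPKM with shYap-1 and 94.4 with shYap-2. For this list of 13 genes camera gave adjusted p = 0.629 and 0.642.

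**Figure D3:**
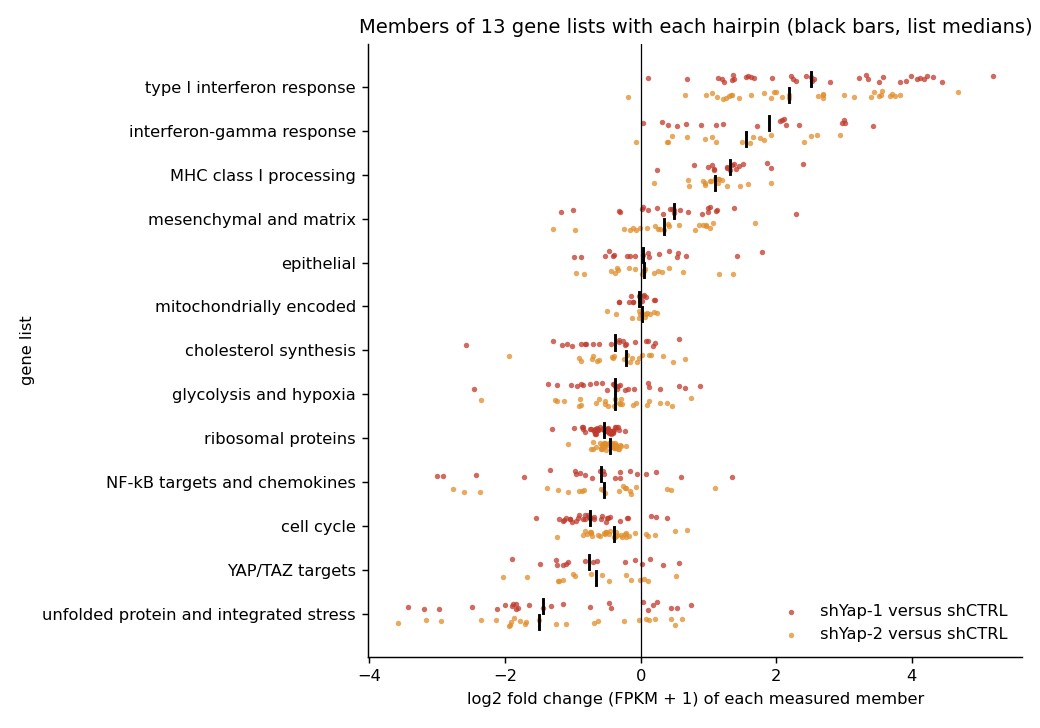
Log2 fold change (FPKM + 1) of each measured member of 13 gene lists with shYap-1 and shYap-2 against shCTRL (points, genes; black bars, medians). Interferon and MHC class I members lie to the right of 0, and most ribosomal protein, cell cycle and stress response members to its left.

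Of 20 lists tested, camera called 12 with shYap-1 (5 higher, 7 lower) and 10 with shYap-2 (3 higher, 7 lower). With an estimated correlation 8 and 0 were called; the 0 had 6 lists at unadjusted p under 0.05. Fry, which asks whether a list's genes move on balance 1 way, called 17 and 17. Without shYap-1 replicate 2, the ribosomal protein list alone was called with shYap-1 and an estimated correlation (adjusted p = 0.0416). The calls with an estimated correlation given above for YAP/TAZ targets, MHC class I, interferon, stress response, cell cycle and sterol synthesis then ended. Unless given, the number of members past the threshold was the same adjusted over the list alone.

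Across all genes tested with shYap-1, 6943 of 10647 changed (limma, Benjamini-Hochberg adjusted p under 0.05), 4002 higher and 2941 lower, and 1354 of them changed at least 2-fold (944 higher, 410 lower). With shYap-2, 7823 of 10615 changed, 4586 higher and 3237 lower, and 884 at least 2-fold (659 higher, 225 lower). The values of all 3 replicates lay on 1 side of the controls for 71.2% and 76.6% of genes, where chance gives 10%. Of the called genes, 57.6% and 58.6% rose, and 49.8% and 50.4% with trimmed-mean scaling between libraries. That scaling centres the changes across genes, with medians of -0.018 and 0 instead of 0.073 and 0.076. It therefore cannot tell whether the excess of rises was real. The naming rule ranked shared changes by the smaller of the 2 hairpins' changes. Under it the 10 largest shared falls were those of Trib3, Chac1, Ddit4, Cxcl5, Cxcl1, Ciart (-2.86 and -2.58), Pck2 (-2.69 and -2.54), Gpt2 (-2.58 and -2.51), Slc6a9 (-2.58 and -2.48) and Ccl20.

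The hairpins changed largely shared genes. Of 10583 genes tested with both, 3830 rose with both and 2739 fell with both, 6569 in all (3291 and 3284 with trimmed-mean scaling), and 0 were called in opposite directions (limma, 0 also at unadjusted p under 0.05 in both). Lists of these sizes drawn independently would share 2610 genes in the same direction (1711 higher and 899 lower). Simulated groups without any change, set against shared simulated controls, shared 0. Hardly any gene passes where none changes, so this 0 was given in advance and says nothing of the overlap. Across genes, the log2 fold changes had Pearson r 0.981 and Spearman rho 0.977, against a mean r of 0.5 in the simulated groups. Their covariance was 0.407 beside a simulated 0.00566, a difference of 0.401, and 93.4% of genes had the same sign against a simulated 66.7%. The 3 shCTRL libraries serve both comparisons and are too few to give each 2 of its own, so part of the excess overlap can come from them; genes are not independent replicates.

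**Figure D4:**
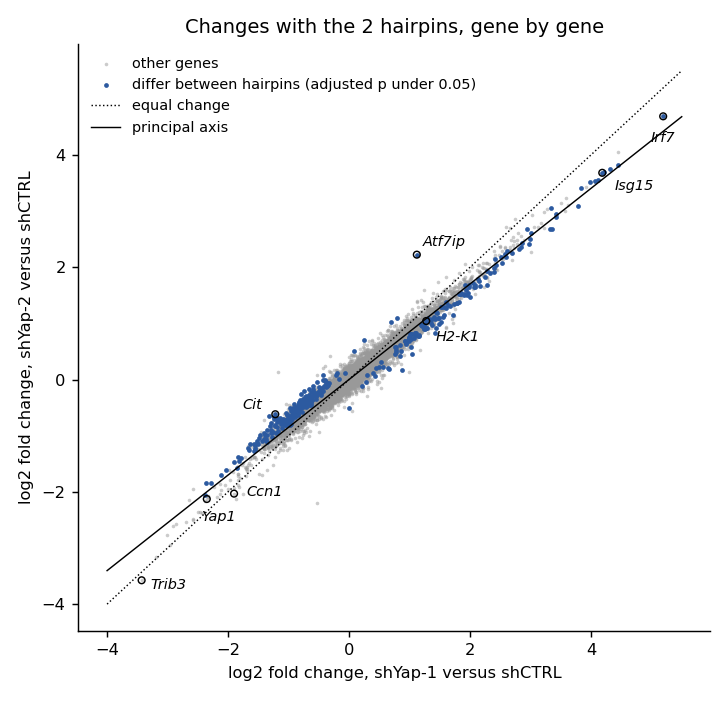
Log2 fold change (FPKM + 1) with shYap-2 against that with shYap-1, 1 point per gene tested in both, with the lines of equal change (dotted) and of the principal axis (solid, slope 0.851). Genes that differ between the hairpins are in blue, and Atf7ip lies above the line of equal change.

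For the mean of both hairpins against shCTRL, in 1 fit of all 9 libraries, Yap1 fell by 2.24 (SE 0.0578, adjusted p = 1.77e-09). Irf7 (4.94), Isg15 (3.93) and Tap1 (2.16) rose, and Trib3 (-3.50), Asns (-1.97) and Ccn1 (-1.97) fell. Here 7666 of 10733 genes changed, 4459 higher and 3207 lower, and 1074 at least 2-fold (787 higher, 287 lower). With trimmed-mean scaling 3820 were higher and 3845 lower, and with median-of-ratios scaling 3823 and 3843. All 17 MHC class I genes and 35 of 36 type I interferon genes rose, and all 42 ribosomal protein genes fell. Camera called 12 of 20 lists, and 8 with an estimated correlation: YAP/TAZ targets, MHC class I, both interferon lists, cell cycle, sterol synthesis, stress response and ribosomal proteins (adjusted p = 0.0113 to 0.0309). The non-classical MHC, chemokine, mesenchymal and hypoxia lists lost their call (adjusted p = 0.153, 0.08, 0.363 and 0.171 with an estimated correlation). The values of the 6 knockdown libraries did not overlap those of shCTRL for 66.0% of genes.

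The hairpins differed from each other in a smaller set of genes. Yap1 was 0.22 higher with shYap-2 on the log2 scale, which did not pass (adjusted p = 0.0992). Cell cycle genes were less reduced with shYap-2: 17 of 33 were higher than with shYap-1 and 0 lower (30 higher adjusted over the list alone, median 0.32, adjusted p = 4.86e-25, and 0.000597 with an estimated correlation). Ccna2 (0.40, adjusted p = 0.00846) and Mcm7 (0.38, adjusted p = 0.00878) are examples. Sterol synthesis genes were less reduced too, with 5 of 22 higher (11 adjusted over the list alone, median 0.24), among them Fdps (0.38, adjusted p = 0.00846). Interferon genes were less raised: 15 of 36 type I genes were lower with shYap-2 (28 adjusted over the list alone, median -0.37), and 6 of 18 interferon-gamma genes (9 adjusted over the list alone, median -0.26). After shYap-1 changes were multiplied by the slope of 0.851, the type I list no longer differed past the threshold (residual median 0.045, adjusted p = 0.954 with an estimated correlation), unlike the cell cycle list (0.206, adjusted p = 0.000812). In the MHC class I list 1 of 17 was lower, Tap1 (-0.48, adjusted p = 0.0233), and 12 adjusted over the list alone (median -0.23). Under the naming rule, the largest differences upward were Atf7ip (1.10, limma, adjusted p = 0.0108), Diexf (0.68), Cit (0.60), the deubiquitinase gene Usp1 (0.58) and Tfap4 (0.54). Atf7ip had 25.5 ± 6.0 FPKM (SD, n = 3) with shYap-1 and 55.1 ± 7.95 (SD, n = 3) with shYap-2, and rose with both against shCTRL (1.12 and 2.22). Against shCTRL, Diexf (-1.32 and -0.64), Cit (-1.22 and -0.62), Usp1 (-1.25 and -0.66) and Tfap4 (-1.24 and -0.70) fell with both hairpins, less with shYap-2. Downward the largest under that rule were Serpinb9b (-0.69), Ifit3b (-0.66), Ifit3 (-0.65), Usp18 (-0.62) and Pqlc2 (-0.57), all of which rose with both hairpins against shCTRL. The rule asks for a mean of at least 5 FPKM, which left out Tnfrsf14 (-0.69, limma, adjusted p = 0.0413; 3.66 FPKM with shYap-1).

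Of 10733 genes tested for this difference, 353 passed (limma, adjusted p under 0.05), 207 higher and 146 lower with shYap-2, and 1 at least 2-fold. The replicate values of the hairpins did not overlap for 25.9% of genes, where chance gives 10%. The count changed with the libraries used: 3, 1 and 1 genes passed without shYap-2 replicate 1, 2 or 3, and 196, 1646 and 80 without shYap-1 replicate 1, 2 or 3. It was 203, 179 and 184 without shCTRL replicate 1, 2 or 3, and 1177 with the GC trend removed from each library. The calls of all 10 genes named for the largest differences ended without any one of the shYap-2 libraries, while the folds stayed similar. The same holds for the members of the cell cycle, sterol, interferon and MHC class I lists: without any one shYap-2 library 0 of them passed (limma; 29 of 33 cell cycle genes at unadjusted p under 0.05 each time), with cell cycle medians of 0.31, 0.33 and 0.32 and type I interferon medians of -0.41, -0.34 and -0.42. Ccna2 then had adjusted p = 0.0502, 0.0547 and 0.0567. Without replicate 1, 2 or 3 of shYap-2, Atf7ip had 1.13, 1.18 and 0.99 (adjusted p = 0.0627, 0.0547 and 0.0656) and Serpinb9b -0.67, -0.71 and -0.69 (adjusted p = 0.0502, 0.0547 and 0.0567). Those of Diexf, Usp1, Pqlc2, Ifit3b, Ifit3 and Usp18 ended in other settings as well, such as a pseudocount of 0.1 for the last 3 (adjusted p = 0.0517, 0.176 and 0.168). Camera called 10 of 20 lists (3 higher, 7 lower), and 5 with an estimated correlation. The calls lost were ribosomal proteins (median 0.10, adjusted p = 0.12 with an estimated correlation), non-classical MHC (-0.14, adjusted p = 0.12), immune ligands (-0.07, adjusted p = 0.131), mesenchymal genes (-0.14, adjusted p = 0.193) and TGF-beta response (-0.13, adjusted p = 0.204). The 10 other lists, YAP/TAZ targets (median -0.003, adjusted p = 0.982) and stress response (-0.03, adjusted p = 0.982) among them, were not called.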

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

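Of the tests weighed here, those on leukocytes, on scaling between libraries and on a response to hairpin RNA were chosen after the result was seen, as were the removal of the GC trend per library and the slope taken without interferon and MHC genes. A test of the difference between the hairpins singled out 353 genes and 5 gene lists that passed with an estimated correlation too. Cell cycle genes (median difference shYap-2 minus shYap-1 0.318) and sterol synthesis genes (0.242) were less reduced with shYap-2. MHC class I genes (-0.234), type I interferon genes (-0.368) and interferon-gamma genes (-0.26) were less raised. The adjusted p with an estimated correlation were 0.000597, 0.0055, 0.015, 0.0198 and 0.014. Without shYap-1 replicate 2, which stands apart from its fellow replicates, the adjusted p = 0.0169, 0.0305, 0.0421, 0.0732 and 0.0421, so the type I interferon list no longer passed. Its difference did not shrink without that library: the median was -0.434, and 29 of 35 genes were lower with shYap-2 (limma, adjusted p under 0.05).

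Cell cycle genes were weighed for 3 explanations. If shYap-2 gave the same response on a smaller scale, the list would not differ after shYap-1 changes are multiplied by the slope of 0.851 across genes, but its residual median was 0.206 (adjusted p = 0.000812 with an estimated correlation), so 1 overall scaling is not enough. Without shYap-1 replicate 2 the residual median was 0.223 at a slope of 0.866 (camera, adjusted p = 0.0282 with an estimated correlation). The difference itself also stayed without that library (median 0.305) and with the GC trend removed from each library (median 0.303).

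For the 3 lists that were less raised with shYap-2, no difference beyond that scaling was detected. Their residual medians were -0.035 for MHC class I, 0.045 for type I interferon and 0.012 for interferon-gamma genes (adjusted p = 0.341, 0.954 and 0.534 with an estimated correlation). Taken without the interferon and MHC lists, the slope was again 0.851 and these residuals -0.035, 0.046 and 0.013 (adjusted p = 0.346, 0.945 and 0.537). Sterol synthesis (0.159), stress response (-0.213) and YAP/TAZ target genes (-0.048) did depart from 1 scaling (camera, adjusted p = 0.00606, 0.00606 and 0.0171 with an estimated correlation). Without shYap-1 replicate 2 these calls ended (adjusted p = 0.0643, 0.0865 and 0.145), while the residual medians stayed similar (0.167, -0.196 and -0.068). At the preset correlation the 3 lists still passed without that library (camera, adjusted p = 1.66e-06, 8.63e-07 and 0.0157).

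The rise of interferon genes with both hairpins was weighed for 3 explanations. Leukocytes in the knockdown cultures would bring their abundant transcripts, but the highest of 7 such genes in any knockdown library was 0.32 FPKM. Outside these 7, Csf1r went from 0.19 FPKM in shCTRL to 0.78 and 0.50, and Itgam from 0.01 to 0.24 and 0.16. Of all 15 leukocyte markers with values, only Cd68 passed 1 FPKM in a group mean, and it fell from 7.79 to 4.25 and 4.52. Scaling between libraries does not account for it, as the lower of the list medians was 2.115 with trimmed-mean scaling. A response to the hairpin RNA and a response to the loss of Yap1 cannot be told apart. The hairpins differ by a median of -0.368 in this list, but shCTRL also carries a hairpin and no sample restores Yap1.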

How the results depend on the processing

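No called named gene, and no called list among those followed, changed sign under any alternative. The balance of called genes did turn with trimmed-mean scaling, to 3458 higher and 3485 lower with shYap-1 and to 3820 and 3845 for the mean. Since that scaling centres the changes across genes, a near-even balance follows from it. Requiring a log2 change of at least 1 left 1354 genes with shYap-1, 884 with shYap-2, 1074 for the mean, 1 between the hairpins and 857 shared by both; this threshold does not apply to lists and was not run for them. With each library left out in turn, the genes that differ between the hairpins ranged from 1 to 1646, the latter without shYap-1 replicate 2. With the GC trend removed, chosen after seeing the data, they were 1177. This contrast takes a common variance per gene from all its libraries, and shYap-1 replicate 2 lay furthest from its fellow replicates. How far that set these counts was not tested. With an estimated correlation 0 lists were called by camera with shYap-2 (6 at unadjusted p under 0.05) and 5 between the hairpins; fry called 17 with shYap-2. With shYap-1, an estimated correlation without shYap-1 replicate 2 left only the ribosomal protein list called. Apart from these and the replicate block, counts of genes stayed within 1.5 times, from 5826 to 7643 with shYap-1, 6636 to 8442 with shYap-2, 6418 to 8425 for the mean and 5554 to 7059 shared by both. Yap1 ranged from -2.465 to -2.296 with shYap-1 and from -2.221 to -2.089 with shYap-2. Among named genes, leaving out a library kept 1490 results, weakened 52 and strengthened 6; for 13 lists followed in 3 comparisons it kept 265, weakened 5 and strengthened 3.

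The labels do not say whether equal replicate numbers pair the samples. With a replicate block 141 genes differed between the hairpins instead of 353, and the cause was not tested. With it 6785, 7808, 7641 and 6476 genes passed with shYap-1, with shYap-2, for the mean and with both. Deviations of libraries with the same number had r from -0.237 to 0.344, and those with different numbers from -0.393 to 0.325. No pairing was seen in these values, but they cannot exclude one. Count-based tools were not run, since the files hold no counts. With 19.55 to 28.3 M fragments per library, genes near 1 FPKM rest on few fragments, and 9 of 127 named genes leave the test when a knockdown library is left out, because they are near 0 in shCTRL. So do 12 members of the interferon lists with shYap-1 and 11 with shYap-2. Results lost in this way are not counted as weakened.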

Other observations

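The 6 gene lists of this part were added after the data were seen. Their p-values were adjusted over these 6 lists alone. They describe lists chosen with the data in view and are no independent test of them. Lysosomal genes rose: 33 of 35 were higher with each hairpin (medians 1.122 and 0.93, adjusted p = 0.0486 and 0.0212 with an estimated correlation). Clu (2.94 and 2.68), Grn (2.13 and 1.80), Hexa (1.88 and 1.6) and Ctsd (1.85 and 1.52), named after their values were seen, are examples. Genes of serine, proline and one-carbon metabolism fell, 14 of 17 with shYap-1 and 15 of 17 with shYap-2 (medians -1.34 and -1.25), among them Mthfd2 (-2.39 and -2.06) and Psat1 (-2.12 and -1.70), while Cbs rose (1.71 and 1.01). This list holds Pck2, Gpt2 and Asns, already among the falls reported above, so its count and its p partly restate them. The adjusted p = 4.99e-08 and 3.41e-08, and adjusted p = 0.0533 and 0.0699 with an estimated correlation. Of 20 cytosolic tRNA synthetase genes, 14 fell with each hairpin (medians -0.69 and -0.67, adjusted p = 3.87e-05 and 2.33e-05, and adjusted p = 0.0533 and 0.0949 with an estimated correlation). Genes of rRNA processing fell, 21 and 20 of 24 (medians -0.53 and -0.36, adjusted p = 0.0262 and 0.0212 with an estimated correlation), with Noc2l (-1.90 and -1.47), Nop56 (-1.19 and -0.84) and Npm1 (-1.02 and -0.78). Histone genes with polyadenylated transcripts rose, 7 of 8 and 6 of 7 (medians 2.30 and 2.27, adjusted p = 0.0043 and 0.0147), but with an estimated correlation the adjusted p = 0.288 and 0.352. Their shCTRL values vary, with a SD above the mean in some, such as Hist2h2aa2 (9.6 ± 11.5 FPKM, SD, n = 3). Circadian clock genes were not called (adjusted p = 0.0718 and 0.0864).

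The fall of ribosomal protein genes with both hairpins was weighed for 3 technical explanations, the last, scaling, chosen after the result was seen. Of 10000 lists matched for abundance and for the exonic length annotated per gene, 0 had a median as low. That length need not be that of the transcript expressed, so a bias by transcript length was not excluded. With the trend on GC content removed, the median nearer 0 of the 2 hairpins was -0.607, and with trimmed-mean scaling it was -0.537. Neither the GC trend nor this scaling accounts for the fall.

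Other splits of the libraries were compared with the real groups. The 6 libraries of a hairpin comparison allow 10 splits into 3 and 3, which cannot give a share under 0.05. With shYap-1 the real split gave 6943 genes and the highest other 0 (limma, 7283 and 291 at unadjusted p under 0.05), so 1 of 10 splits gave as many. With shYap-2 it was 7823 and 0 (limma, 8024 and 54 unadjusted), again 1 of 10, and between the hairpins 353 and 1 (2150 and 1290 unadjusted), again 1 of 10. Every other split of 6 libraries mixes the real groups, so their difference adds to the residual variance. For each hairpin against shCTRL, where most genes changed, the 0 was thus given in advance and is no evidence. For the mean of both hairpins 1 of 100 splits gave as many, with 7666 genes against 7496. That highest other split kept the 3 shCTRL libraries as a group, as did 1 more, and the highest of the rest was 3731.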
